A study of Bos taurus with 40 samples.

How the data were processed

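Messenger RNA was sequenced from muscle biopsies of Holstein-Friesian bulls, a dairy breed of cattle, in 40 libraries. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and purified on columns, and single-end libraries were made with a TruSeq kit. The submitters' processing notes name CASAVA 1.4, TopHat, HTSeq and edgeR and the cattle assembly UMD3.1. The roles and other settings of these tools are not given in the sources used here.

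2 files per library were deposited. The first holds the authors' whole-number read counts for 24616 genes, in the layout HTSeq writes, with 92 entries for spike-in RNAs that were at 0 in every library. The second holds, per the labels and the values, a normalised signal: the authors' counts per 1000000 of an effective library size, for 10882 genes in the period 1 libraries and 10977 in the period 2 libraries. Multiplied back, those values came within 0.000598 of whole counts. Their genes were the genes over 1 count per 1000000 (CPM) in at least 10 libraries of the period. The effective library sizes of the authors lay between 0.842 and 1.41 times the gene counts. The tests used the raw counts, and the normalised values served only to check the counts and to give the authors' gene filter.

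Lines that name no gene were left out of library sizes and tests. Reads outside annotated genes made up 10.0% to 18.7% of the gene, outside-gene and ambiguous reads of a library, and ambiguous reads 0.584% to 1.40%. Counts over genes were between 20.8 M and 33.0 M per library (M, 1000000 counts), with a median of 25.6 M. 5487 genes had no count in any library. No pair of libraries of a group agreed within sampling noise: the smallest chi-square per gene over the pairs was 22.8, so each library was counted as 1 sample. Reads carry no molecular identifiers here, so intervals from counts cover counting error only.

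The labels define 4 groups of 10 libraries: control and restricted bulls, each at day 120 of period 1 and day 15 of period 2. One protocol text gives 20 bulls in all and another 20 bulls per feeding group. The 40 libraries were read as 10 bulls per feeding group sampled at both times, because the title numbers repeat across the times and the second number of the library code differs by 30 between both libraries of every numbered pair. This pairing was checked on the deviations of the log2 CPM from the group means, with the term for 7 libraries described below removed. Libraries with the same number correlated across genes at 0.11 to 0.43 in the control group (median 0.17) and at 0.19 to 0.38 in the restricted group (median 0.29). Libraries with other numbers had medians of -0.02 and -0.03. All 10 pairs in each feeding group were above 0.1. In the restricted group all 10 libraries of each time were closest to their own number. In the control group 5 of 10 libraries of period 1 and 8 of 10 of period 2 were, and other numbers reached 0.34. The numbers were therefore taken to pair the libraries of a bull across the times, less surely in the control group. Without the term, 8 control and 7 restricted pairs were above 0.1. The closest matches were then 4 and 2 of 10 in the control group and 7 and 7 in the restricted group.

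Changed genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion estimates, TMM scaling and the filterByExpr filter (minimum count 10, total 15), which left 12753 genes. All 40 libraries entered one fit with 4 group means, and no block or covariate. 5 contrasts were taken: restricted against control in period 1, previously restricted against control in period 2, period 2 against period 1 in each feeding group, and the difference between the latter 2 changes, called the interaction. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistics. These choices and most alternatives were fixed before the data were examined: DESeq2 1.42.0, limma 3.58.1 with voom, with and without bull as a random effect, other scalings and filters, a fit with the first number of the library code as a factor, fits to the compared groups alone, a replicate block, other thresholds, and leaving out each library.

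Libraries were searched for structure. The first principal component separated 7 libraries that all had under 12% of reads outside genes. A term for these 7 libraries, their removal, the same term without 1 further library, the term with a block for each bull, and the authors' gene filter were added after seeing the data. The deviation analysis for bulls and the cross-fitted share used log2 CPM. The share of counts in the 10 most abundant genes was tested in percent, in Python 3.11.15 with SciPy 1.17.1.

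The share of the restriction difference still present at day 15 was estimated by cross-fitting, which avoids selecting and measuring genes in the same animals. Bulls were split into parts of 5 per feeding group, genes were called with limma in one part at period 1, and the differences at both times were measured in the other part. Parts with fewer than 20 called genes were left out. The edgeR fit was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold among 12753. It recovered 47, 46, 52, 53 and 23 of the former and 88, 88, 84, 83 and 62 of the latter, in the order of the contrasts above, with 10, 5, 12, 2 and 2 false calls. These counts were drawn independently for each gene, without the structure of the 7 libraries or levels of bulls. They therefore do not give the false calls under such structure. Other splits of the real libraries, given below, called up to 1799 genes, and up to 2311 with the term for the 7 libraries. The bull test recovered 172 of 200 simulated genes with 7 false calls. The cross-fitted share came out at 24.3% where 25% had been simulated.

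The files hold Ensembl identifiers and do not pair them with gene symbols. The reference gene table used here is of another assembly, ARS-UCD2.0, and 0 of its 37063 genes carry an Ensembl identifier, so the 24616 identifiers could not be matched to it. The gene lists, cell type markers and individually fixed genes that had been chosen beforehand were therefore not analysed here. The rule for named genes took the largest positive and negative fitted log2 fold changes among changed genes with a mean of at least 1 CPM over the compared libraries. It also asked for a symbol, a condition that had to be dropped, and the list was cut to 2 genes in each direction for the feeding and time comparisons. For the interaction the same genes are given. How the authors' counting treated near-identical gene copies and overlapping genes is not given in the sources used here, so values of such genes are uncertain.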

Results

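The study followed 20 Holstein-Friesian bulls through feed restriction and the return to full feeding. 10 bulls had free access to feed throughout and served as the control group. The other 10 received a limited allowance for 125 days (period 1), set for a growth of 0.6 kg per day, and then free access to feed for 55 days (period 2). All animals ate the same mixture of 70% concentrate and 30% grass silage. Muscle was biopsied on day 120 of period 1, late in the restriction, and on day 15 of period 2, early in the phase in which previously restricted cattle are known to grow faster than continuously fed ones (compensatory growth). Each of the 4 groups had 10 libraries. Mean gene counts were 26.1 ± 1.72 M (M, 1000000 counts; SD, n = 10) in control bulls of period 1, 25.3 ± 3.19 M in control bulls of period 2, 25.2 ± 3.24 M in restricted bulls of period 1 and 26.9 ± 2.63 M in restricted bulls of period 2. With 12753 genes tested, the spread between animals had a median SD of 0.24 to 0.27 log2 units per gene within groups. These values are after removal of the term for 7 libraries given under processing.

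The strongest axis of variation among the libraries followed neither feeding nor time. The first principal component held 23.9% of the variance and set 7 libraries, with scores of 44.5 to 64.7, apart from the other 33, with scores of -24.2 to 7.72. Those 7 libraries had 10.0% to 11.2% of reads outside genes, against 13.3% to 18.7% in the others. They were control bull 6 in period 1, control bulls 2, 3 and 8 in period 2, restricted bulls 1 and 9 in period 1 and restricted bull 10 in period 2. Between the 7 libraries and the rest, 7971 of the 12753 genes differed by the edgeR quasi-likelihood test, 3606 of them higher and 4365 lower in the 7. The set was noticed in the same expression values, so this test was bound to call many genes. The number of changed genes in each of the 5 comparisons is therefore given also with a term for these libraries and from the 33 other libraries alone. Counts of 2-fold changes are given without the term, and overlaps of comparisons are not given from the 33 libraries.

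**Figure D1:**
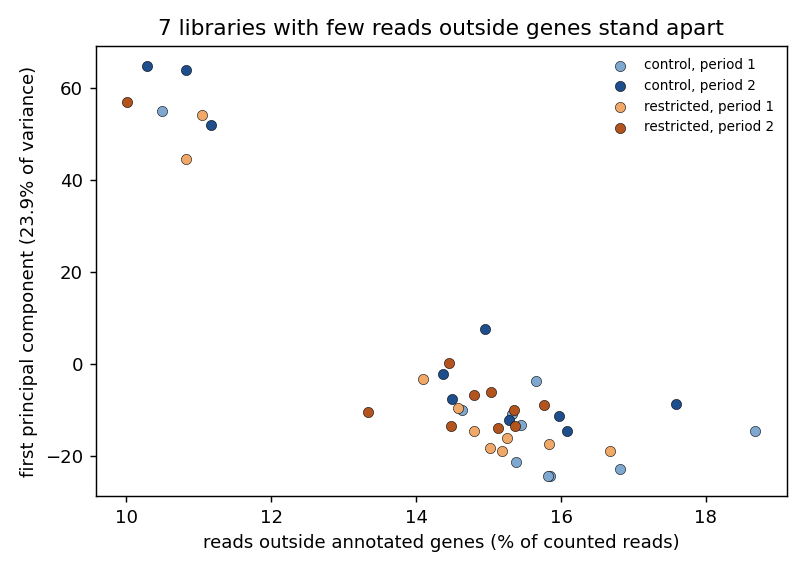
Each point is 1 of the 40 libraries, placed by its reads outside annotated genes (% of gene, outside-gene and ambiguous reads) and its score on the first principal component of log2 CPM, coloured by group. The 7 libraries under 12% lie at 44.5 or higher on the component and include members of all 4 groups.

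The first comparison asked how muscle of restricted bulls differed from that of fully fed bulls late in the restriction. 1249 genes (9.79% of those tested) differed, 573 higher and 676 lower in restricted bulls. Most differences were small, with a median size of 0.52 log2 units, or 1.44-fold. Large differences were more often decreases, with 142 genes at least 2-fold lower and 51 at least 2-fold higher in restricted muscle. ENSBTAG00000027425 was higher in restricted bulls at 3.48 ± 1.23 CPM (SD, n = 10) against 1.13 ± 0.609 CPM in control bulls, and all 10 restricted libraries lay above the highest control library. Its fitted log2 fold change was 1.63 ± 0.26 (SE; edgeR adjusted p = 8.24e-05). ENSBTAG00000007665 rose from 0.514 ± 0.232 to 1.63 ± 1.01 CPM, a log2 fold change of 1.66 ± 0.44 (edgeR adjusted p = 0.0119), with 7 of 10 restricted libraries above every control library. In a fit with the first number of the library code as a factor the adjusted p of this gene was 0.134, and over all alternatives it ranged from 0.00277 to 0.134. All 4 libraries with first number 1 were of control bulls in period 1, so that fit gave them a level of their own. Its period 1 comparison therefore rested on the other control libraries.

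Among genes with a mean of at least 1 CPM over both groups, the largest decreases came from genes that varied strongly among control bulls. ENSBTAG00000014911 averaged 3.19 ± 5.35 CPM in control bulls, with a range of 0.0809 to 17.2 CPM, and 0.124 ± 0.215 CPM in restricted bulls, where 4 of 10 libraries had no count. Its log2 fold change was -4.66 ± 0.95 (edgeR adjusted p = 0.00119), -3.69 without control bull 4 and -5.47 without restricted bull 1. ENSBTAG00000010564 averaged 17.9 ± 27.4 CPM in control and 1.86 ± 2.04 CPM in restricted bulls, a log2 fold change of -3.28 ± 0.72 (edgeR adjusted p = 0.0024). Control bull 4 reached 92.5 CPM of this gene, and without its library the log2 fold change was -2.38. For both genes all 10 restricted libraries lay below the control median and 7 below the lowest control library.

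The direction of the restriction response depended in part on scaling. With TMM factors 45.9% of the changed genes were higher in restricted bulls, while with total counts alone the split was 285 higher and 1102 lower, or 20.5% higher. DESeq2 size factors gave 651 higher and 589 lower, and a filter at a mean of 1 CPM gave 626 and 543, so which direction held more genes was not settled. Total counts moved the median log2 fold change of all genes to -0.14, from -0.04 with TMM. With a term for the 7 libraries 2273 genes differed, among them all 1249 in the same direction, and the 33 other libraries alone gave 2102, of which 1156 were shared.

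**Figure D2:**
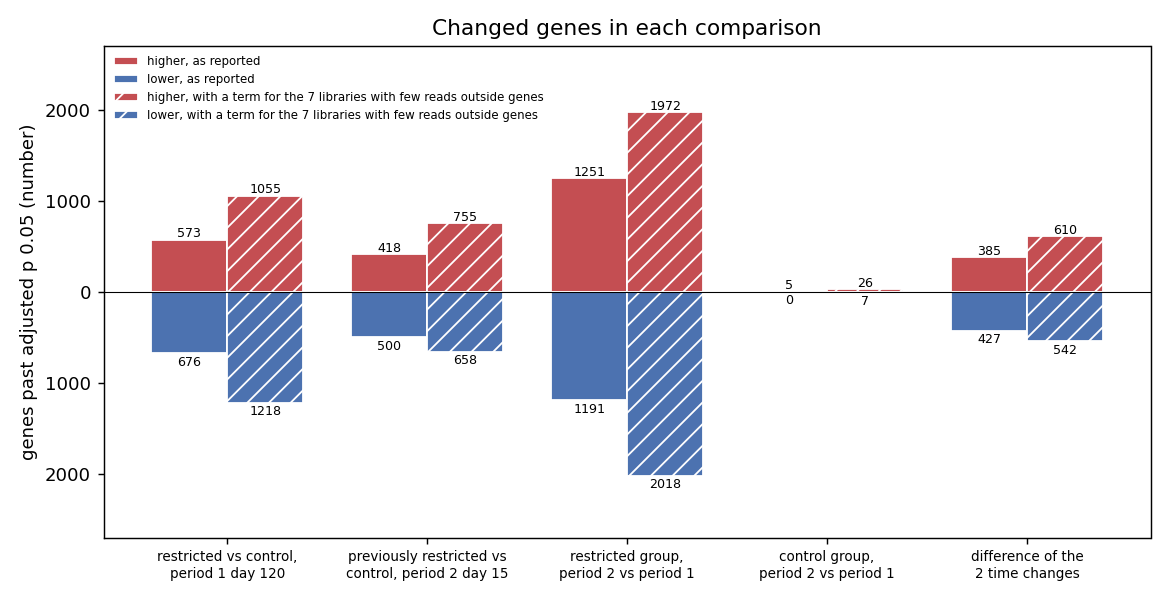
Bars give the number of genes past an adjusted p of 0.05 in each comparison (edgeR quasi-likelihood test, 12753 genes), higher above the 0 line and lower below it, without (plain) and with (hatched) a term for the 7 libraries with few reads outside genes. The change of the control group over time reached 5 and 33 genes, against 2442 and 3990 in the restricted group.

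The second comparison asked what still or newly separated the animals 15 days after full feeding resumed. 918 genes (7.20%) differed between previously restricted and control bulls, 418 higher and 500 lower, with a median size of 0.47 log2 units. 44 genes were at least 2-fold higher and 64 at least 2-fold lower. ENSBTAG00000039719 was at 13.5 ± 16.7 CPM (SD, n = 10) in previously restricted bulls, with a range of 2.66 to 54.1 CPM, and at 1.50 ± 0.892 CPM in control bulls. Its log2 fold change was 3.15 ± 0.47 (edgeR adjusted p = 0.000132), and all 10 previously restricted bulls lay above the control median. Of these, 5 lay above the highest control library. Without restricted bull 10 the log2 fold change was 2.56. ENSBTAG00000026418 averaged 15.5 ± 20.8 against 1.83 ± 3.73 CPM, a log2 fold change of 3.07 ± 0.71 (edgeR adjusted p = 0.00678), again with all 10 animals above the control median. For this gene 4 of the 10 lay above the highest control library. Its log2 fold change was 4.52 without control bull 10 and 2.45 without restricted bull 2.

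Among the decreases, ENSBTAG00000009599 averaged 0.183 ± 0.294 CPM in previously restricted and 2.75 ± 4.34 CPM in control bulls, a log2 fold change of -3.77 ± 0.94 (edgeR adjusted p = 0.0114), with all 10 previously restricted libraries below the control median. In the control group 1 of 10 libraries had no count of this gene, so none could lie below every control library. The log2 fold change was -4.75 without restricted bull 7 and -2.89 without control bull 2. Without control bull 2 in period 2 its adjusted p was 0.0503, from the 33 other libraries 0.082, with the first code number as a factor 0.0779 and with limma and voom 0.258, over a range of 0.0087 to 0.258 in the alternatives. This decrease was not new at day 15. In restriction the log2 fold change of the gene was -6.17 ± 1.30 (edgeR adjusted p = 0.0016, and 2.13e-05 to 0.066 in the alternatives). There 7 of 10 restricted libraries had no count. ENSBTAG00000018223 had a log2 fold change of -3.17 ± 0.74 (edgeR adjusted p = 0.00754) that rested on few control animals. Control bull 7 reached 91.9 CPM and control bull 4 18.7 CPM, while 6 of 10 previously restricted libraries lay above the control median of 1.01 CPM. Without the library of control bull 7 the log2 fold change was -1.26 (adjusted p = 0.142). DESeq2 gave -1.13 (adjusted p = 0.185), and over the alternatives the adjusted p ranged from 0.00535 to 0.564.

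With total counts alone the day 15 split moved from 45.5% higher to 25.4%, with 201 genes higher and 589 lower. It was 439 and 449 with DESeq2 size factors and 471 and 425 with a filter at a mean of 1 CPM. The term for the 7 libraries gave 1413 genes, 881 of them shared with the 918 in direction, and the 33 other libraries gave 856, of which 561 were shared. Leaving out single libraries gave 572 to 1357 genes, 572 without restricted bull 9 and 609 without restricted bull 8 in period 2, and 1357 without restricted bull 10 in period 2, which is among the 7 libraries.

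**Figure D3:**
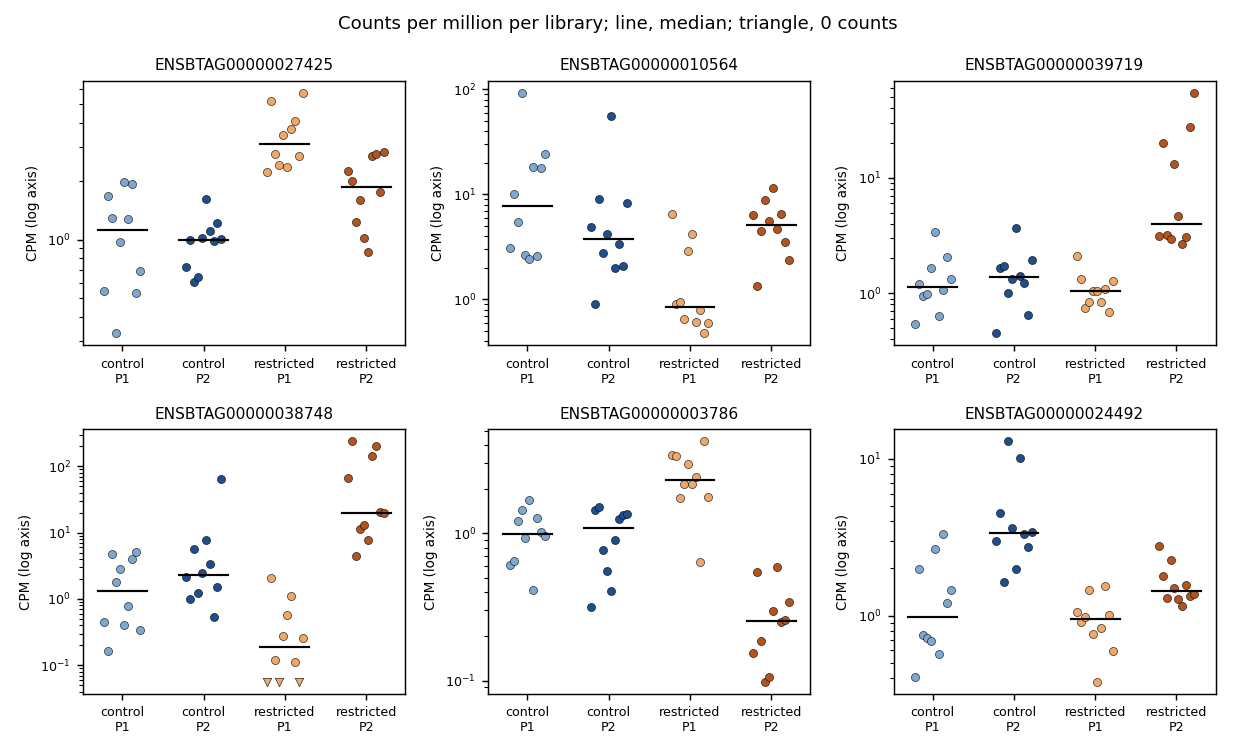
Points are CPM of 6 genes in each of the 40 libraries (log axes; 10 libraries per group; P1, day 120 of period 1; P2, day 15 of period 2), lines are group medians, and triangles mark 0 counts. ENSBTAG00000038748 lies between 4.50 and 236.8 CPM in the 10 restricted bulls of period 2, and ENSBTAG00000003786 between 0.0983 and 0.591 CPM in the same libraries.

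The third comparison followed the restricted group from day 120 of restriction to day 15 of full feeding. It was the broadest response, with 2442 changed genes (19.1%), 1251 higher and 1191 lower after feeding resumed. The median size was 0.54 log2 units. Increases were more often large, with 214 genes at least 2-fold higher and 131 at least 2-fold lower. ENSBTAG00000038748 rose from 0.45 ± 0.66 to 72.4 ± 88.5 CPM (SD, n = 10), in 10 of 10 bulls, a log2 fold change of 7.31 ± 1.04 (edgeR adjusted p = 3.28e-06). Animals differed widely after feeding resumed, from 4.50 to 236.8 CPM, and without restricted bull 2 in period 1 the log2 fold change was 7.97. ENSBTAG00000016121 went from a single count in the whole restricted group to 1515 counts, and rose in 9 of 10 bulls. The ratio of pooled counts was 1338, with an exact 95% interval for counting error alone of 239.8 to 52891. Restricted bull 2 held 899 of the 1515 counts. The fitted log2 fold change, which depends on the prior count here, was 9.39 in edgeR (adjusted p = 9.28e-05), 8.13 without that library and 5.31 by limma with voom. In the control group the fitted change was 4.53 ± 1.36 (adjusted p = 0.133), and the interaction of 4.86 ± 3.16 was not past the threshold (adjusted p = 0.377), so a difference between the feeding groups was not shown for this gene.

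ENSBTAG00000003786 fell from 2.49 ± 1.03 to 0.283 ± 0.17 CPM, a log2 fold change of -3.11 ± 0.33 (edgeR adjusted p = 2.00e-08). ENSBTAG00000004860 fell from 8.97 ± 8.76 to 1.22 ± 0.594 CPM, a log2 fold change of -2.87 ± 0.43 (edgeR adjusted p = 5.21e-06). Both fell in 10 of 10 bulls. The total counts split was 1569 higher and 686 lower, or 69.6% higher against 51.2% with TMM, and with DESeq2 size factors 1184 and 1241. The term for the 7 libraries gave 3990 genes, 2439 of them shared with the 2442 in direction, and the 33 other libraries gave 3591, of which 2304 were shared.

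The fourth comparison followed the control group over the same interval under constant feeding. 5 genes were past the threshold in edgeR, all higher in period 2, although 2439 genes had an unadjusted p under 0.05 where 638 would be expected by chance. DESeq2 called 123 genes and limma with voom 5. ENSBTAG00000024492 rose from 1.37 ± 0.982 to 4.73 ± 3.73 CPM (SD, n = 10), in 9 of 10 bulls, a log2 fold change of 1.80 ± 0.34 (edgeR adjusted p = 0.0162). With each bull as a replicate block its adjusted p was 0.12, over a range of 0.000292 to 0.171 in the alternatives. It was 0.054 without control bull 7 in period 1, and 0.0634 without control bull 4 and 0.069 without control bull 7 in period 2. At day 15 ENSBTAG00000024492 was lower in previously restricted than in control bulls, past the threshold in edgeR. That log2 fold change was -1.54 ± 0.33 (edgeR adjusted p = 0.00412, and 0.000477 to 0.0502 in the alternatives). Over time in the restricted group the gene changed by 0.77 ± 0.35 (edgeR adjusted p = 0.121). Its interaction of -1.03 ± 0.49 was not past the threshold (edgeR adjusted p = 0.204). A rise particular to control bulls was therefore not shown. ENSBTAG00000018563 had a log2 fold change of 3.33 ± 0.67 (edgeR adjusted p = 0.0325), set by control bull 7 at 174.1 CPM against 1.42 to 9.81 CPM in the other control libraries of period 2. Without that library the log2 fold change was 0.61 (adjusted p = 0.259), and with each bull as a replicate block 0.85 (adjusted p = 0.281), over a range of adjusted p from 0.0153 to 0.36 in the alternatives. Leaving out control bull 1, 3, 4, 5, 7, 9 or 10 in period 1 left its log2 fold change at 3.26 or more and gave adjusted p of 0.0622, 0.0605, 0.0767, 0.0693, 0.0693, 0.0777 and 0.0583. The remaining 3 genes rose by 1.30 ± 0.25, 1.03 ± 0.19 and 0.52 ± 0.09 log2 units (edgeR adjusted p = 0.0162, 0.0151 and 0.0116). With each bull as a replicate block the first of these had an adjusted p of 0.12 and the others 0.0135 and 0.0192. With the first code number as a factor the values were 0.101, 0.0754 and 0.0754, so 0 of the 5 genes were past the threshold in that fit. It called 8 others and had 2452 genes at an unadjusted p under 0.05. In that fit all 4 libraries of number 1, from control bulls in period 1, had a level of their own. The change in control bulls therefore rested, in period 1, on the other control libraries. Over the alternatives the adjusted p ranged from 0.000292 to 0.12, 0.000203 to 0.0754 and 0.000154 to 0.0754. That of the first was also 0.054 without control bull 7 and 0.056 without control bull 9 in period 1, and 0.069 without control bull 7 in period 2.

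The number of genes changed in the control group was unstable. The paired fit with each bull as a replicate block called 3 genes, 2 of them among the 5, the term for the 7 libraries 33, and the 33 other libraries 90. With the term and without control bull 7 in period 2 edgeR called 0 genes, with 1379 at an unadjusted p under 0.05. Leaving out 1 library at a time gave 2 to 279 genes. In period 1 the count was 34 without bull 2, 279 without bull 6, 2 without bull 7, 8 without bull 8 and 3 without bull 9. In period 2 it was 30 without bull 1, 17 without bull 2, 26 without bull 3, 28 without bull 5, 69 without bull 6, 2 without bull 7, 19 without bull 8, 35 without bull 9 and 39 without bull 10.

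The interaction tested directly whether the change over time differed between feeding groups. It was past the threshold for 812 genes (6.37%), 385 with a more positive and 427 with a more negative change in the restricted group, at a median size of 0.74 log2 units. With total counts alone 329 were more positive and 272 more negative, and with the term for the 7 libraries 610 and 542, so which direction held more genes was not settled. Among the genes named above that passed this test, the largest difference was that of ENSBTAG00000038748, with a log2 interaction of 5.17 ± 1.26 (edgeR adjusted p = 0.00888). Its change in the control group was 2.14 ± 0.81 (adjusted p = 0.198). The interaction was 6.83 without control bull 10 in period 2, 5.83 without restricted bull 2 in period 1, and 4.73 from the 33 other libraries (adjusted p = 0.051, over a range of 0.000949 to 0.051 in the alternatives). ENSBTAG00000039719 rose by 3.61 ± 0.49 in the restricted group and by 0.14 ± 0.48 in the control group, an interaction of 3.48 ± 0.67 (edgeR adjusted p = 0.00123). Without restricted bull 10 in period 2 its change in the restricted group was 3.02 and the interaction 2.89. ENSBTAG00000003786 had an interaction of -3.06 ± 0.44 (edgeR adjusted p = 3.80e-05) and changed by -0.05 ± 0.30 in the control group. The term for the 7 libraries gave 1152 genes, 764 of them shared with the 812 in direction, and the 33 other libraries gave 698, of which 512 were shared. The count was 1226 without control bull 6 in period 1 and 1274 without restricted bull 10 in period 2, which are both among the 7 libraries.

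The comparisons were then set against each other to follow the genes changed by restriction. Of the 1249 genes, 742 moved back past the threshold in the restricted group by day 15 of full feeding, 357 of the 573 that had been higher and 385 of the 676 that had been lower, and 0 moved further away. Independent lists would share 53.5 and 66.3 genes in these directions. Both comparisons use the restricted libraries of period 1, which alone gives a negative relation. Across genes, which are not independent replicates, the fold changes correlated at -0.68, against -0.50 in simulated unchanged groups, and the covariance was -0.113 against -0.0235. The simulated genes were drawn independently, without the structure of the 7 libraries or levels of bulls. Their range of correlations, -0.53 to -0.47, can therefore be narrower than that of real unchanged groups. With the shared libraries divided between the comparisons the correlation was -0.53, the covariance -0.099 and the median numbers of opposite calls 117 and 119. With the term for the 7 libraries the opposite calls were 666 and 737, against 166.9 and 188.3 for independent lists, and 3 genes in each direction moved further. Without the term, the interaction was past the threshold opposite to the restriction difference for 435 of the 1249 genes. It was past the threshold in the same direction for 0. The interaction also shares the period 1 libraries with the restriction comparison, which alone gives a negative relation. Return to the level of control bulls was not tested by these counts.

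At day 15, 101 of the 1249 genes still differed from control bulls in the same direction, 50 higher and 51 lower, where independent lists of these sizes would share 18.8 and 26.5. Both feeding comparisons use the same bulls. Lasting levels of bulls can put genes on both lists in the same direction, which the numbers for independent lists leave out. A further 61 differed in the opposite direction, 30 from higher to lower and 31 from lower to higher, against 22.5 and 22.2 for independent lists. With the term for the 7 libraries, 169 and 101 genes kept their direction, against 62.5 and 62.8, while the opposite calls of 51 and 65 lay below the 54.4 and 72.1 of independent lists. ENSBTAG00000003786 was among the 61 genes, 1.28 ± 0.29 log2 units higher in restriction (edgeR adjusted p = 0.00356) and changed to -1.78 ± 0.33 at day 15 (adjusted p = 0.00118). ENSBTAG00000009599 kept its direction, with the values given above. ENSBTAG00000027425 kept its direction too, at 0.94 ± 0.27 (edgeR adjusted p = 0.0254). In period 2 its adjusted p was 0.0505 without control bull 3 and 0.0543 without restricted bull 8, and from the 33 other libraries it was 0.102, over a range of 0.0102 to 0.102 in the alternatives. The fold changes of both feeding comparisons correlated at 0.16 across genes with a covariance of 0.0207. The correlation lay within the range of -0.42 to 0.46 (median 0.13) from 40 permutations of the feeding labels among bulls, which had a median covariance of 0.00655. These permutations kept both libraries of a bull together, and 0 genes were on both lists in any of them. Their median number of changed genes was 0 in each comparison. They therefore do not show how many shared genes lasting levels of bulls add to lists of the real sizes. Of the 918 genes that differed at day 15, 756 had not been past the threshold in restriction.

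In the cross-fitted estimate, genes called in one part of the bulls differed by a median of 0.69 log2 units between restricted and control bulls of the other part in period 1, and by 0.04 at day 15, in the direction of the original change. The share left at day 15 was 7.18% with an SD of 13.9 percentage points over 79 usable parts and a range of -44% to 33.4%. These spreads are over overlapping parts of the same bulls and give no sampling interval. The median share was -4.86% for genes higher and 13.1% for genes lower in restriction. With the term for the 7 libraries the share was 7.94% with an SD of 9.35 over 100 parts, and 4.26% and 10.1% by direction.

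**Figure D4:**
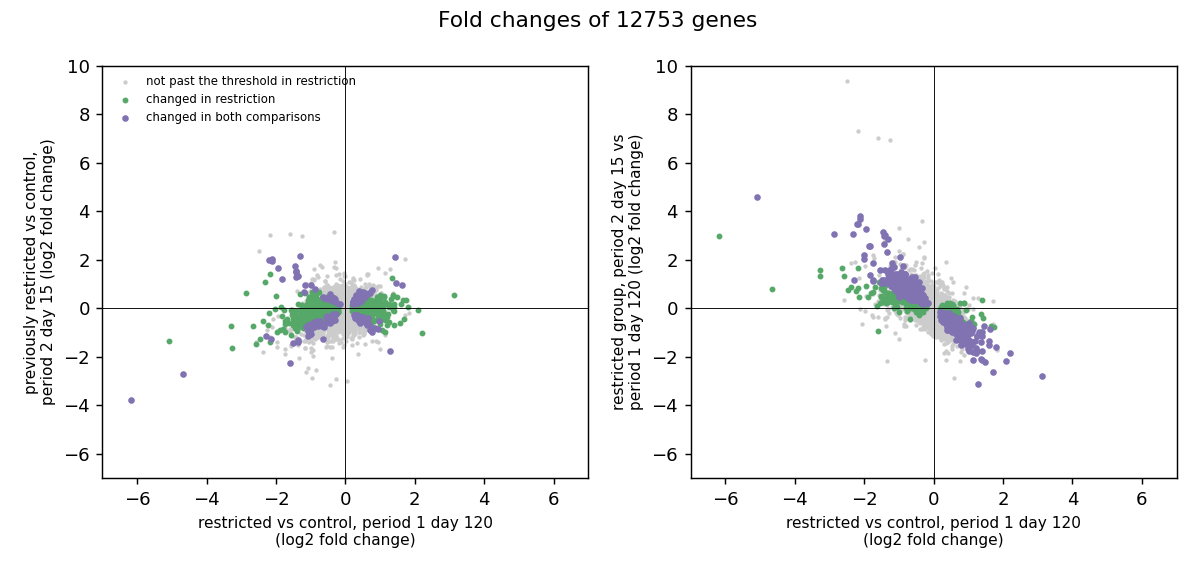
Each point is 1 of 12753 genes, placed by its log2 fold change in restriction (horizontal) and, vertically, in previously restricted against control bulls at day 15 (left) or in the restricted group over time (right). Green points are changed genes of the restriction comparison and purple points are changed in both comparisons of the panel; on the right all 742 purple points have opposite signs, and on the left 101 share and 61 oppose the sign.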

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

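The tests of explanations in this part, and the splits with the term for the 7 libraries, were chosen after the results they bear on had been seen. In 72 tests of library measures and named genes, 13 gaps between a library and the nearest other of its group were large against the range of the group. For normally distributed values not chosen beforehand, chance gives such a gap in about 1 of 20 groups, or 3.6 here. The named genes, however, were chosen from these same values for large fold changes, which can favour genes carried by 1 library. Whether the 13 gaps exceed chance was therefore not shown. 2 of these gaps were in reads outside genes and 1 in the share of the most abundant genes, and they belong to the 7 libraries that stand apart. Control bull 6 in period 1 had 10.5% of reads outside genes against 14.6% to 18.7% in its group (gap 0.506 of the range), and its 10 most abundant genes took 30.6% of counts against 25.5% to 26.9% (gap 0.718). Restricted bull 10 in period 2 had 10.0% of reads outside genes against 13.3% to 15.8% (gap 0.578). Control bull 8 in period 2 had 32.6 M gene counts against 21.4 to 26.7 M (gap 0.522).

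The 7 libraries may come from a batch of library preparation or sequencing. They carried 2 of the 10 first code numbers, all 4 libraries of number 6 and 3 of the 4 of number 5, and a random choice of 7 libraries would fall within 2 numbers with a probability of 1.93e-05. What that number stands for is not stated in the labels. The feeding group or the time of biopsy is argued against, since at most 3 of the 7 fell in any 1 of the 4 groups. Lasting differences between bulls are argued against as well, since 0 bulls had both biopsies among the 7. A difference in RNA quality or biopsy content that followed the same numbers stays open.

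Several named genes had a single library far from the rest. The gaps of genes were taken on log2 CPM, while the levels are given in CPM. Control bull 7 in period 2 had a TMM factor of 1.43 against 0.874 to 1.11 in its group (gap 0.569) and reached 174.1 CPM of ENSBTAG00000018563 against 1.42 to 9.81 CPM (gap 0.604). Whether this library holds other tissue was not tested, since the files give no gene names, so what its values of this gene and of ENSBTAG00000018223 stand for, and the counts over time in control bulls that rest on it, stay uncertain. ENSBTAG00000004860 was at 13.2 CPM in control bull 4 in period 2, against 1.4 to 3.86 CPM (gap 0.555), and at 33.4 CPM in restricted bull 10 in period 1, against 3.67 to 9.29 CPM (gap 0.582). ENSBTAG00000003786 was at 0.64 CPM in restricted bull 8 in period 1, against 1.74 to 4.22 CPM (gap 0.518). ENSBTAG00000026418 was at 12.4 CPM in control bull 10 in period 2, against 0.246 to 1.51 CPM (gap 0.564). ENSBTAG00000016121, near 0 in most libraries, was at 0.445 CPM in control bull 5 in period 1 (gap 0.79), at 10.5 CPM in control bull 1 in period 2 (gap 0.547) and at 0.0403 CPM, a single count, in restricted bull 4 in period 1, where the other 9 libraries had 0 (gap 1 of the range).

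The change over time differed between the feeding groups for 812 genes. Among named genes the log2 interaction was 3.48 for ENSBTAG00000039719, 4.66 for ENSBTAG00000026418, 5.17 for ENSBTAG00000038748, -3.06 for ENSBTAG00000003786, -2.06 for ENSBTAG00000004860 and -3.02 for ENSBTAG00000018563. The last rests on control bull 7 in period 2, without which it was -0.31 (adjusted p = 0.606). Its adjusted p also passed 0.05, up to 0.057, without any 1 of 11 other libraries, and ranged from 0.0352 to 0.678 in the alternatives. That of ENSBTAG00000026418 was 0.0713 without control bull 9 in period 1, with log2 interactions of 6.11 without control bull 10 and 4.04 without restricted bull 2 in period 2. It was 0.194 with limma and voom, 0.165 with bull as a random effect, 0.0553 with the first code number as a factor, 0.109 from the 33 other libraries and 0.0603 with the term and without control bull 7, over a range of 0.0016 to 0.194 in the alternatives. That of ENSBTAG00000004860 was 0.0579 without control bull 4 in period 2 and 0.0553 without restricted bull 10 in period 1, and 0.0581 with limma and voom, over a range of 0.00766 to 0.0581. The uneven spread of the 7 libraries over the groups is argued against as the whole cause, since 764 of the 812 genes stayed past the threshold in the same direction with a term for them. From the 33 other libraries alone, with fewer per group, 512 of the 812 did, so it stays open for the genes lost in either fit. The single library of control bull 7 in period 2 is argued against as well, since 784 genes stayed in the same direction without it. A difference due to the change of feeding, which the design names, remains a hypothesis. The interaction was planned, while these other explanations were tested after its result had been seen.

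Other splits of the same libraries were tried for each count, 100 per comparison with the real one included. Over time the libraries of a bull were exchanged within pairs, so every split parted all 10 pairs, and for the interaction bulls were reassigned with both libraries. For restricted against control bulls in period 1, 1 of 100 splits, the real one, gave 1249 genes or more and the highest other gave 1. Chance is argued against there, and 1 of 100 is the smallest share that these splits can give. At day 15, 2 of 100 gave 918 or more. The highest other split gave 1027 genes and put all 4 libraries of the low outside-gene set on one side. With the term for the 7 libraries in every split that split gave 0 genes, the real one 1413 and the highest other 108. For the restricted group over time 1 of 100 splits, the real one, reached 2442 genes and the highest other gave 946. With the term these were 3990 and 2311. For the control group over time 6 of 100 splits gave 5 genes or more, so chance cannot be excluded. The highest of these, 1799 genes, again put all 4 of its libraries from the set of 7 on one side and points to the structure of the samples. With the term that split gave 0 genes, and 3 of 100 splits gave 33 or more, the real one with 33 among them. For the interaction 1 of 100 splits reached 812, and the highest other gave 17.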

How the results depend on the processing

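Changed-gene counts within 1.5 times those reported are left out here. The term for the 7 libraries, their removal, the combined fits with the term and the authors' gene filter were chosen after seeing the data. The cause of each move was not tested, except where a threshold changes the count by construction. The first code number was in part confounded with group and time. All 4 libraries of number 1 were of control bulls in period 1, and all 4 of number 9 were of period 2. In period 1, restricted against control, the count of 1249 became 2207 with the first code number as a factor, 2273 with the term, 2102 without the 7 libraries, 2535 with the term and without control bull 7 in period 2, 532 at 1.5-fold or more and 1884 at an adjusted p under 0.10. At day 15 the 918 became 579 with only the compared groups, 1413 with the term, 302 at 1.5-fold or more and 1625 at 0.10. The 2442 of the restricted group over time became 3990 with the term, 4571 with the replicate block and the term, 4247 with the term and without control bull 7, and 1085 at 1.5-fold or more. The 5 of the control group over time became 22 with DESeq2 size factors, 13 with total counts, 123 with DESeq2, 10 with bull as a random effect, 20 with a filter at 1 CPM, 12 without robust estimation, 8 with the first code number, 3 with only the compared groups, 3 with the replicate block, 33 with the term, 90 without the 7 libraries, 8 with the replicate block and the term, 0 with the term and without control bull 7 (1379 genes at an unadjusted edgeR p under 0.05) and 110 at 0.10. The 812 of the interaction became 1630 with the first code number, 1692 with the replicate block and the term, 1414 with the term and without control bull 7, and 1476 at 0.10. The 742 genes changed in restriction and the other way in the restricted group over time became 1403 with the term. With the shared libraries divided they became 236. The 101 that kept their direction at day 15 became 270 with the term.

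Leaving out 1 library at a time gave 987 to 1581, 572 to 1357, 2072 to 2605, 2 to 279 and 636 to 1274 genes in the same order. With each bull as a replicate block the restricted group had 2581 and the interaction 944 genes, and outside the control group the paired fit moved no other count by over 1.5 times. Of the calls of named genes over time in restricted bulls and in the interaction it ended 1, the interaction of ENSBTAG00000018563 (-0.54, adjusted p = 0.605). Between feeding groups, title numbers join different animals: same-numbered libraries correlated at medians of -0.01 and -0.02, with 0 and 2 of 10 libraries closest to their own number, and a replicate block on that number gave 661 and 78 genes. No named gene reversed under any alternative that was run. In the feeding comparisons ENSBTAG00000010564, ENSBTAG00000026418 and ENSBTAG00000024492 lost the threshold with that number block alone, among the alternatives other than leaving out a library. The gene list tests and the marker composition were not run. Depth was 20.8 M gene counts or more in every library. ENSBTAG00000016121, with 1 count over the restricted group of period 1, is limited by depth.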

Other observations

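The tests in this part were chosen after the data had been seen. Many genes kept a level particular to the bull at both biopsies. With the group means and the term for the 7 libraries removed, 821 of 12753 genes (6.44%) differed among bulls beyond the difference between the biopsies of a bull, by an F test on log2 CPM with Benjamini-Hochberg adjustment. Of these, 167 had an intraclass correlation of at least 0.8. Without the term the number was 396. A hypothesis is that these genes mark lasting differences between bulls. Chance pairing of libraries is argued against, since 20 random pairings within the feeding groups gave at most 2 genes. Both libraries of a bull made in one batch is argued against too, since 1 of the 20 bulls had both under one first code number. Sequence differences between a bull and the reference that change how reads align were not tested and stay open.

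The 10 most abundant genes took a larger share of counts in restricted muscle once the 7 libraries were left out. In period 1 the share was 27.5% ± 1.12 (SD, n = 8) in restricted and 26.2% ± 0.561 (n = 9) in control bulls, by an exact two-sided permutation test p = 0.0103 and adjusted p = 0.0206 over 2 comparisons. At day 15 it was 27.2% ± 1.28 (n = 9) and 25.9% ± 1.58 (n = 7), with an exact permutation p of 0.0764. With all libraries (n = 10 per group) the differences were 1.16 and 0.569 percentage points, with adjusted p of 0.145 and 0.542 by permutation tests with 100000 resamples.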
